A study of Homo sapiens with 9 samples.

How the data were processed

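The labels describe 9 RNA-seq libraries of HEK293T cells carrying PRPS1-HA-dTAG and PRPSAP1-V5-BromoTag, 3 treated with DMSO, 3 with dTAG47 and 3 with AGB1, the compounds at 500 nM for 24 h. Groups and replicate numbers were taken from the sample titles and the treatment labels. Per the labels' protocols, RNA was purified on columns, messenger RNA was selected with poly-T beads, fragmented and copied with random hexamers, and libraries were made and sequenced by a service provider. The deposited files hold whole-number counts per Ensembl gene for each library, not normalized. Per the submitters' processing notes the tools were HISAT2 and DESeq2 and the build hg38; versions, the counting tool and its strand setting are not given in the sources used here. The gene models in the deposited files match GENCODE release 29 (Ensembl 94) in identifier, start, end and strand for 58735 of 58735 genes, so coordinates are those of GRCh38. Gene names were taken from the files. Each entry names a gene, and 25698 genes had a count in no library.

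Total counts were 32898739, 31937133 and 37420878 in DMSO 1 to 3, 35240765, 44803380 and 31046698 in dTAG47 1 to 3, and 37250551, 27964128 and 31051174 in AGB1 1 to 3. A count of 3 corresponds to between 0.0670 and 0.107 CPM at these depths. The common biological coefficient of variation was 11.0%, and the median among genes at 5 CPM or more was 7.35%, so that the median standard error of a log2 fold change in these genes was 0.09. Reads carry no molecular identifiers, so counting limits cover counting error only.

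The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as the design, which left 18319 (14043 protein-coding), libraries were scaled by TMM, and one quasi-likelihood model with a coefficient per group was fitted to all 9 libraries, so that the 3 groups share one estimate of the spread. The contrasts were dTAG47 minus DMSO, AGB1 minus DMSO and dTAG47 minus AGB1, tested with glmQLFTest; p-values were adjusted by Benjamini-Hochberg over the tested genes, and 0.05 was the threshold. Fold changes are on the log2 scale, and the standard error is the absolute log2 fold change divided by the square root of F. Levels are CPM with TMM-scaled library sizes, given as mean ± SD over the 3 libraries of a group. The 39 gene lists, covering nucleotide metabolism, histones and chromatin, the cell cycle, stress responses, central metabolism and markers of other cell types, were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists, and again with the correlation estimated per list. When it estimates the correlation, camera also uses the residual degrees of freedom of the 9 libraries in place of those of the tested genes. A list can therefore miss the threshold under that setting without a high correlation. Within each list, p-values were also adjusted over its own members. The groups, the design, the lists, the other settings and the rule for named genes were fixed before the data were examined. By that rule the text names PRPS1, PRPS2, PRPSAP1 and PRPSAP2 always; the 6 largest rises and 6 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries; and up to 3 genes past the threshold per list. List members given as examples beyond this rule were chosen after their values were seen.

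Fold changes against the shared DMSO libraries were compared with 50 simulations of unchanged groups. Each simulation drew all 9 libraries anew around the mean of each gene over the 9, with genes drawn independently. Shares of counts were compared by two-sided exact permutation tests. Sharing of sequence between a called gene and other genes was measured on its longest transcript, as the percentage of 75-base words found in transcripts of other genes. Counts of a gene and its closest copy were summed and refitted where at least 50% of words were shared. The fit was tested on simulated counts for dTAG47 against DMSO in 17879 genes, with 200 genes changed and the 20 cytosolic aminoacyl-tRNA synthetases shifted by 0.25 as a list: 38.8% of genes changed 1.25-fold, 68.7% of those changed 1.5-fold and 72.7% of those changed 2-fold were recovered, with 8 false calls among the other 17659 genes. The 200 genes were drawn from those with a mean of at least 1 CPM. The simulated fit called 137 genes, so recovery may be lower in data with fewer calls. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors, library sizes alone, no count filter, a filter of 1 CPM in 3 libraries, only the 2 groups compared, protein-coding genes only, the replicate number as a block, removal of the gene length trend with and without that block, and leaving out each of the 9 libraries. Removal of the GC trend by lowess (span 0.3), a fit of the 6 compound-treated libraries against DMSO, the summed counts of copies and 3 further gene lists were added after the data were seen. Shared words were counted in Python 3.11.15 and figures were drawn with matplotlib 3.10.9.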

Results

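Gene expression was measured by poly(A)-selected RNA sequencing in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. The cells express PRPS1 fused to an HA epitope and a dTAG degron, and PRPSAP1 fused to a V5 epitope and a BromoTag degron. PRPS1 is a phosphoribosyl pyrophosphate (PRPP) synthetase, which makes the ribose phosphate donor used to build purine, pyrimidine and pyridine nucleotides, and PRPSAP1 is a non-catalytic protein associated with the same enzyme complex. The design asked how the transcriptome responds when either protein is removed. dTAG47 was used to deplete PRPS1 and AGB1 to deplete PRPSAP1, each at 500 nM for 24 h, next to a DMSO control. dTAG47 recruits the ubiquitin ligase substrate receptor CRBN to the dTAG, and AGB1 recruits VHL to the BromoTag. Each of the 3 groups holds 3 libraries. Total counts per library ranged from 27964128 to 44803380, and 18319 of the 58735 genes listed were tested.

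The 9 libraries were similar in composition. Mitochondrial transcripts took 2.25% ± 0.110 of counts (SD, n = 3) in DMSO, 2.16% ± 0.216 with dTAG47 and 2.12% ± 0.152 with AGB1. Messenger RNAs of cytosolic ribosomal proteins took 7.28% ± 0.409, 7.15% ± 0.0614 and 7.28% ± 0.132. None of these shares separated a pair of groups beyond the spread of the libraries (two-sided exact permutation tests, p from 0.2 to 1, where 0.1 is the smallest p that 3 against 3 libraries can give). The first principal component of the genes at 5 CPM or more held 22.1% of the variance, and its ends were DMSO 1 (score −13.1) and dTAG47 1 (score 11.4) rather than whole groups. In the same libraries, deviations from the gene mean followed the GC content of the transcripts most steeply: Spearman's rho across genes, which are not independent replicates, was −0.378 in DMSO 1 and 0.623 in dTAG47 1. In the 3 AGB1 libraries this rho lay between −0.0269 and 0.0497. On the second component (15.25% of the variance) DMSO 1 to 3 scored 2.73, 5.83 and 10.1, and dTAG47 1 scored 4.22. The remaining libraries had negative scores, from −6.18 to −1.63. Libraries of one group differed far beyond counting noise (chi-square per degree of freedom from 6.05 to 16.3), so no library was a second copy of another. The labels do not say whether the libraries of a group came from separate cultures. The p-values below therefore measure only the spread between these libraries, which may be technical.

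The transcripts of the degron-tagged genes did not pass the threshold in any comparison. The compounds act on the proteins, so these mRNA levels do not check the depletion. PRPS1 (ENSG00000147224, GRCh38 chromosome X, 107628424 to 107651026, plus strand) was at 103 ± 3.77 CPM in DMSO, 110 ± 3.49 with dTAG47 and 109 ± 0.556 with AGB1 (SD, n = 3). Its log2 fold change was 0.09 with dTAG47 (95% interval −0.04 to 0.21) and 0.08 with AGB1 (−0.05 to 0.20). PRPSAP1 (ENSG00000161542, chromosome 17, 76309486 to 76384521, minus strand) was at 29.4 ± 6.64 CPM in DMSO, 29.6 ± 2.68 with dTAG47 and 29.1 ± 1.67 with AGB1, with intervals of −0.23 to 0.25 and −0.26 to 0.22. The paralogous synthetase PRPS2 (ENSG00000101911, chromosome X, 12791355 to 12824222) had log2 fold changes of −0.04 with dTAG47 and −0.03 with AGB1. PRPSAP2 (ENSG00000141127, chromosome 17, 18840085 to 18931287), the other associated protein, had −0.02 and 0.13. The largest of these values, −0.14 for PRPSAP2 between dTAG47 and AGB1, had an edgeR adjusted p of 0.999.

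With dTAG47, the genes HMOX1, CHAC1 and SLC7A5 were higher than in DMSO. HMOX1, heme oxygenase, which breaks down heme and is a classical target of the oxidative stress regulator NRF2, rose from 39.5 ± 1.49 CPM to 58.3 ± 4.64 (SD, n = 3), a log2 fold change of 0.56 (SE 0.08, edgeR adjusted p = 0.00127). CHAC1, a glutathione-degrading enzyme induced by the transcription factor ATF4, rose by 0.80 (SE 0.16, adjusted p = 0.0330), from 6.68 ± 1.22 to 11.7 ± 1.22 CPM. SLC7A5, a transporter of large neutral amino acids, rose by 0.28 (SE 0.05, adjusted p = 0.0213). WNT5A, a secreted WNT ligand, fell by 0.54 (SE 0.09, adjusted p = 0.0112), from 42.5 ± 1.70 to 29.2 ± 2.42 CPM. ALDH1A2, which makes retinoic acid, fell by 0.37 (SE 0.07), as did FOXO4, a forkhead transcription factor (SE 0.07).

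In all, 6 genes rose and 5 fell with dTAG47 in edgeR's quasi-likelihood test, while 1333 genes had an unadjusted p under 0.05, where 916 would be given by chance. The other genes that rose were RHOB, a small GTPase (0.35, SE 0.06), JUN, a subunit of the AP-1 transcription factor (0.32, SE 0.06), and MRPL23, a mitochondrial ribosomal protein (0.67, SE 0.12). MRPL23 stood at 68.9 CPM in dTAG47 1 against 44.8 and 46.2 in the other dTAG47 libraries. GPR89B, a Golgi pH regulator, had the steepest fall, −1.09 (SE 0.18), but 73.7% of its 75-base words also occur in its copy GPR89A, and the summed count of both fell short of the threshold (−0.27, SE 0.15, edgeR adjusted p = 0.738). MT-RNR1, the mitochondrial small-subunit ribosomal RNA, which was named after its values were seen, fell by 0.36 (SE 0.07), with DMSO 3 and dTAG47 2 overlapping at 749.9 and 754 CPM. Of the 11 calls, HMOX1 held without each of the 9 libraries in turn and the other 10 ended without at least 1 of them; the total was 2 without dTAG47 1, 3 without DMSO 2, 5 without DMSO 1, 6 without dTAG47 3 and 20 without DMSO 3. DESeq2 called 47 genes but not MT-RNR1, MRPL23 or GPR89B, limma called 10 but not CHAC1, 22 were called with the GC trend removed, and a fit of the 6 libraries alone called 4, which kept HMOX1 and lost CHAC1, SLC7A5, RHOB, JUN, MRPL23, ALDH1A2, FOXO4 and MT-RNR1.

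**Figure D1:**
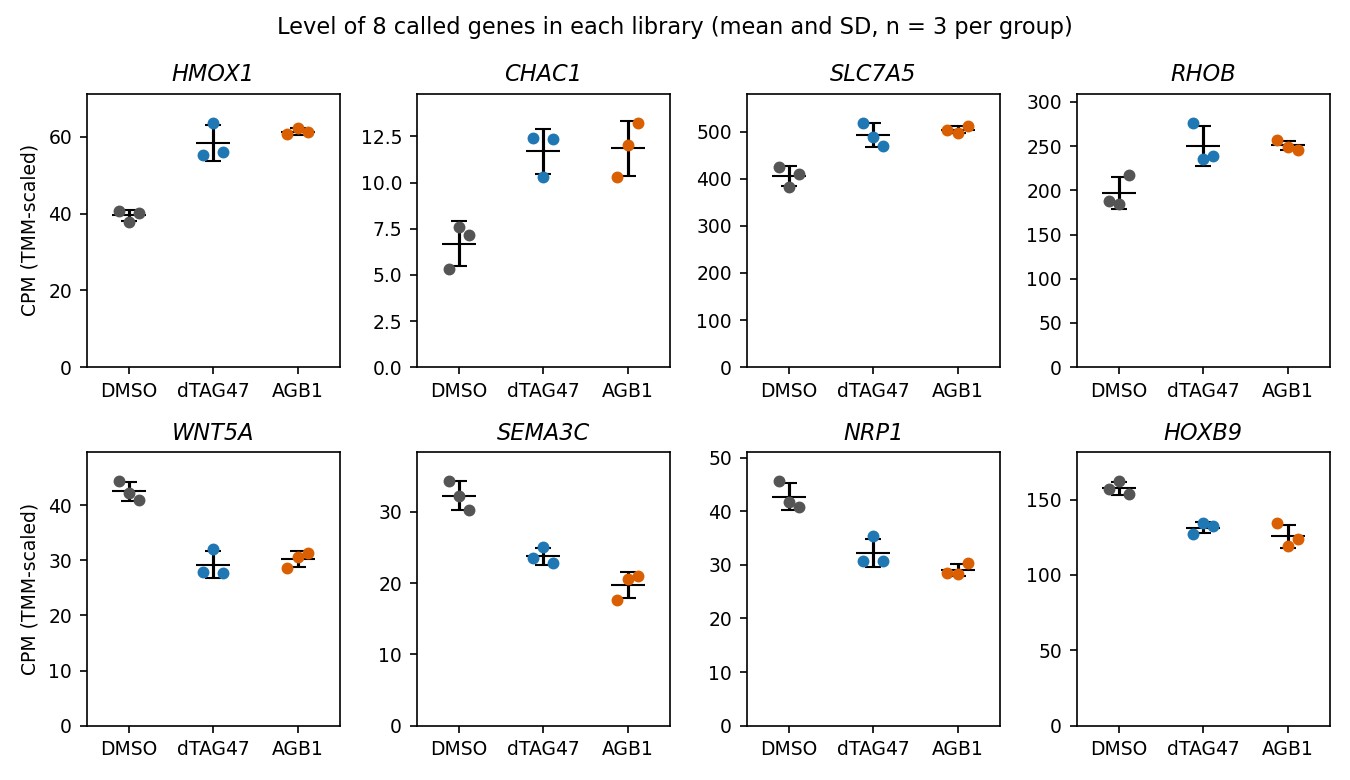
Level in TMM-scaled CPM of 8 genes in each of the 9 libraries, grouped by DMSO, dTAG47 and AGB1; points are libraries and bars the mean and SD (n = 3). HMOX1, CHAC1, SLC7A5, RHOB and WNT5A passed the threshold with both compounds, SEMA3C, NRP1 and HOXB9 with AGB1; HMOX1 stood at 39.5 CPM in DMSO, 58.3 with dTAG47 and 61.4 with AGB1.

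As a group, the targets of the integrated stress response regulator ATF4 were higher with dTAG47 at the preset correlation (camera adjusted p = 4.96e-08). With an estimated correlation the list did not pass (adjusted p = 0.108). Of 30 tested ATF4 targets, 25 had a positive fold change (median 0.13), SLC7A5 and CHAC1 rose over all genes, and 5 rose when adjusted over the list alone, the other 3 being SESN2 (0.29, SE 0.06), PPP1R15A (0.33, SE 0.10) and EIF4EBP1 (0.20, SE 0.07). NRF2 targets were positive in 13 of 18 genes (median 0.06, camera adjusted p = 0.00278, and adjusted p = 0.108 with an estimated correlation); HMOX1 rose over all genes, and HMOX1 and the ferritin heavy chain FTH1 (0.24, SE 0.06) when adjusted over the list alone. Lysosomal and autophagy genes under mTORC1 and TFEB were positive in 19 of 24 (median 0.10, camera adjusted p = 0.00136, and adjusted p = 0.108 with an estimated correlation); 0 rose over all genes and the sialidase NEU1 (0.31, SE 0.08) rose when adjusted over the list alone.

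Among immediate early genes, 13 of 22 were positive with dTAG47, and JUN rose over all genes. JUN, JUND (0.41, SE 0.09), KLF6 (0.30, SE 0.08) and DUSP1 (0.31, SE 0.10) rose when adjusted over the list alone. The list's median was 0.09 and its mean −0.00303, and camera put it upward (adjusted p = 0.00602, and adjusted p = 0.327 with an estimated correlation). In the pentose phosphate pathway, which supplies ribose 5-phosphate to PRPP synthetase, 8 of 9 genes were positive (median 0.11), with 0 past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 0.00806, and adjusted p = 0.327 with an estimated correlation). Cytosolic ribosomal proteins were negative in 57 of 78 genes (median −0.04) and G2/M and mitosis genes in 32 of 40 (median −0.05), both at a camera adjusted p of 0.00278. With an estimated correlation these became adjusted p = 0.766 and adjusted p = 0.327. No ribosomal protein gene passed in either adjustment, whereas the mitotic genes CENPE (−0.26), ASPM (−0.24) and TTK (−0.29) fell when adjusted over the list alone and 0 mitotic genes over all genes. Targets of p53 (26 genes) had a median of −0.07 and a camera adjusted p of 0.213; GADD45A rose and SESN1 (−0.41) and TP53INP1 (−0.54) fell when adjusted over the list alone, and 0 over all genes. The camera adjusted p was 0.258 for aminoacyl-tRNA synthetases, 0.537 for serine and one-carbon genes, 0.366 for glycolysis and 0.853 for the respiratory chain, with 0 genes in either adjustment. The lists past the threshold were 7 of the 39, 5 upward and 2 downward, and 0 held with an estimated correlation. The ATF4, NRF2 and mTORC1 lists held without each library, although the NRF2 median was 0.0297 without dTAG47 2 (adjusted p = 0.0236). The ribosomal protein median was −0.0900 without DMSO 1 (adjusted p = 1.28e-13) and −0.0101 without DMSO 3, so its size rests on the DMSO libraries. Ribosomal proteins ended without DMSO 2 (adjusted p = 0.106) or DMSO 3 (0.809), G2/M without dTAG47 1 (0.150, median −0.0267), immediate early genes without DMSO 1 (0.0528) or dTAG47 1 (0.135, median 0.0130), and the pentose phosphate pathway without DMSO 1 (0.0825, median 0.0589). With the GC trend removed the median was −0.0263 for G2/M (adjusted p 0.0453) and 0.0677 for the pentose phosphate pathway (adjusted p 0.0382).

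HMOX1, CHAC1 and SLC7A5 were also higher with AGB1 than in DMSO. HMOX1 rose from 39.5 ± 1.49 to 61.4 ± 0.818 CPM (SD, n = 3), a log2 fold change of 0.64 (SE 0.08, edgeR adjusted p = 0.000126), and CHAC1 rose by 0.82 (SE 0.16, adjusted p = 0.0207). SLC7A5 (0.31, SE 0.05), RHOB (0.35, SE 0.06), FTH1 (0.30, SE 0.06) and the transcription factor gene MYC (0.29, SE 0.06) also rose. The guidance cue SEMA3C fell by 0.71 (SE 0.10, adjusted p = 0.00114), from 32.3 ± 1.99 to 19.8 ± 1.85 CPM, and its co-receptor NRP1 fell by 0.55 (SE 0.09, adjusted p = 0.00354). DHRS3, a retinaldehyde reductase, fell by 0.67 (SE 0.11), the secreted glycoprotein FSTL1 by 0.43 (SE 0.07), WNT5A by 0.49 (SE 0.09) and the homeobox gene HOXB3 by 0.53 (SE 0.11).

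In all, 10 genes rose and 9 fell with AGB1 in edgeR's test, and 1421 had an unadjusted p under 0.05. Ribosomal protein genes RPL36 (0.28, SE 0.05) and RPLP1 (0.22, SE 0.04) rose, and CENPE, a kinetochore motor, fell by 0.34 (SE 0.07). The 78 cytosolic ribosomal protein genes as a list did not pass (camera adjusted p = 0.492, median −0.00114, mean 0.00872, test upward), and RPL36, RPLP1 and RPL38 rose when adjusted over the list alone. Named after their values were seen, the homeobox gene HOXB9 fell by 0.32 (SE 0.06) and the nuclear receptor NR2F1 by 0.41 (SE 0.08). The chaperone HSPA1A was called at 0.61 (SE 0.12), but it shares 71.2% of its 75-base words with HSPA1B, which stood at 524 ± 24.5 CPM with AGB1 against 38.8 ± 2.70 for HSPA1A, so its own count is uncertain; their sum (0.22, SE 0.06, edgeR adjusted p = 0.269) is nearly all HSPA1B and does not settle it. The splicing factor U2AF1, named after its values were seen, was called at 2.02 (SE 0.39) from 23.4, 47.6 and 7.93 CPM in the AGB1 libraries, the last within the DMSO range of 5.27 to 8.13, and 98.4% of its words occur in its copy U2AF1L5. FTH1 shares 62.4% of its exonic bases with the opposite-strand gene BEST1 (0.727 CPM) and 30.8% of its words with 12 pseudogenes, RPL36 shares 17.6% of its exonic bases with HSD11B1L on the same strand, and HOXB3 overlaps HOXB4, HOXB6 and antisense genes of its cluster, so these counts are uncertain to that extent. HMOX1, SEMA3C, DHRS3, NRP1 and FSTL1 held without each library in turn, and the other 14 calls ended without at least 1; the total was 6 without AGB1 3, 7 without DMSO 2, 9 without AGB1 2, 10 without DMSO 1 and 55 without DMSO 3. DESeq2 called 81 genes but not U2AF1, limma called 16 but not CHAC1, HOXB3 or U2AF1, 47 were called with the GC trend removed, and MYC ended on library sizes alone and HOXB3 with the gene length trend removed. A fit of the AGB1 and DMSO libraries alone called 22 genes and kept all 19.

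ATF4 and NRF2 targets were higher as groups with AGB1 at the preset correlation. Of 30 ATF4 targets, 27 were positive (median 0.13, camera adjusted p = 4.44e-11, and adjusted p = 0.0501 with an estimated correlation). SLC7A5 and CHAC1 rose over all genes and 9 rose when adjusted over the list alone, among them ATF4 itself (0.13, SE 0.04), the cystine transporter SLC7A11 (0.37, SE 0.11) and ATF3 (0.29, SE 0.07). NRF2 targets were positive in 17 of 18 (median 0.11, camera adjusted p = 1.88e-10, and adjusted p = 0.0124 with an estimated correlation). HMOX1 and FTH1 rose over all genes, and SLC7A11, the ferritin light chain FTL (0.12, SE 0.05) and the thioredoxin reductase TXNRD1 (0.14, SE 0.05) joined them when adjusted over the list alone; NQO1, a standard NRF2 target, was at −0.16 (SE 0.14). p53 targets were negative in 22 of 26 (median −0.11, camera adjusted p = 0.000398, and adjusted p = 0.184 with an estimated correlation), in a line whose p53 is bound by large T antigen. SESN1 (−0.43, SE 0.12) and TP53INP1 (−0.54, SE 0.16) fell when adjusted over the list alone and 0 over all genes, while CDKN1A was at 0.15 (SE 0.09).

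Several metabolic gene lists passed the threshold with AGB1. Cytosolic aminoacyl-tRNA synthetases were positive in 16 of 20 (median 0.07, camera adjusted p = 0.00366, and adjusted p = 0.234 with an estimated correlation), with FARSB (0.22) and GARS (0.17) rising when adjusted over the list alone and 0 over all genes. Serine and one-carbon genes were positive in 15 of 20 (median 0.08, camera adjusted p = 0.0317, and adjusted p = 0.201 with an estimated correlation) and pentose phosphate genes in 9 of 9 (median 0.09, camera adjusted p = 0.0222, and adjusted p = 0.237 with an estimated correlation), each with 0 past the threshold over all genes and 0 adjusted over the list alone. Glycolysis genes were positive in 16 of 21 (median 0.05, camera adjusted p = 0.0437), nuclear-encoded respiratory chain genes in 24 of 38 (median 0.04, camera adjusted p = 0.0412) and mTORC1 and TFEB targets in 18 of 24 (median 0.05, camera adjusted p = 0.0351). With an estimated correlation these became adjusted p = 0.329, adjusted p = 0.589 and adjusted p = 0.201, and 0 of their genes passed over all genes or adjusted over the list alone.

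Among immediate early genes with AGB1, MYC rose over all genes, and MYC, JUN, ATF3 and DUSP1 when adjusted over the list alone. The list's median was 0.01 and its mean −0.07, and camera put it upward (adjusted p = 0.0205, and adjusted p = 0.237 with an estimated correlation). This median depended on the setting: it was −0.00478 with the GC trend removed, −0.000653 on library sizes alone, 0.118 with a filter of 1 CPM in 3 libraries and 0.0882 without AGB1 2, with the test upward each time. G2/M and mitosis genes were negative in 26 of 40 (median −0.04, camera adjusted p = 0.0317, and adjusted p = 0.311 with an estimated correlation); CENPE fell over all genes, and CENPE, TTK (−0.33) and ASPM (−0.21) when adjusted over the list alone. With AGB1, 12 of the 39 lists passed, 10 upward and 2 downward, not all described here, and the NRF2 list alone held with an estimated correlation. The ATF4, NRF2 and p53 lists held without each library, and the other 9 ended without at least 1. The total was 3 without AGB1 3, 5 without DMSO 1 and 7 without AGB1 2. In addition, glycolysis, G2/M and the mTORC1 list ended without DMSO 2 (adjusted p = 0.110, 0.0554 and 0.0641), as did the respiratory chain list (0.0571), glycolysis without AGB1 1 (0.0728), and the serine (0.0706) and mTORC1 lists (0.0558) without DMSO 3. Without DMSO 1 the medians were 0.0176 for glycolysis, 0.00421 for the respiratory chain, 0.0571 for the pentose phosphate pathway, 0.0455 for serine genes and −0.0183 for G2/M, and without DMSO 3 they were 0.0733 for glycolysis and 0.130 for the pentose phosphate pathway. Without AGB1 3 the median was 0.0377 for the synthetases and 0.0538 for the pentose phosphate pathway, and without AGB1 2 it was 0.0478 for serine genes. With the GC trend removed, glycolysis (0.142) and G2/M (0.0544) ended, glycolysis and the respiratory chain ended on library sizes alone (both 0.0764) or with upper-quartile factors (0.0505 and 0.0501), and the respiratory chain with the gene length trend removed (0.0625).

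**Figure D2:**
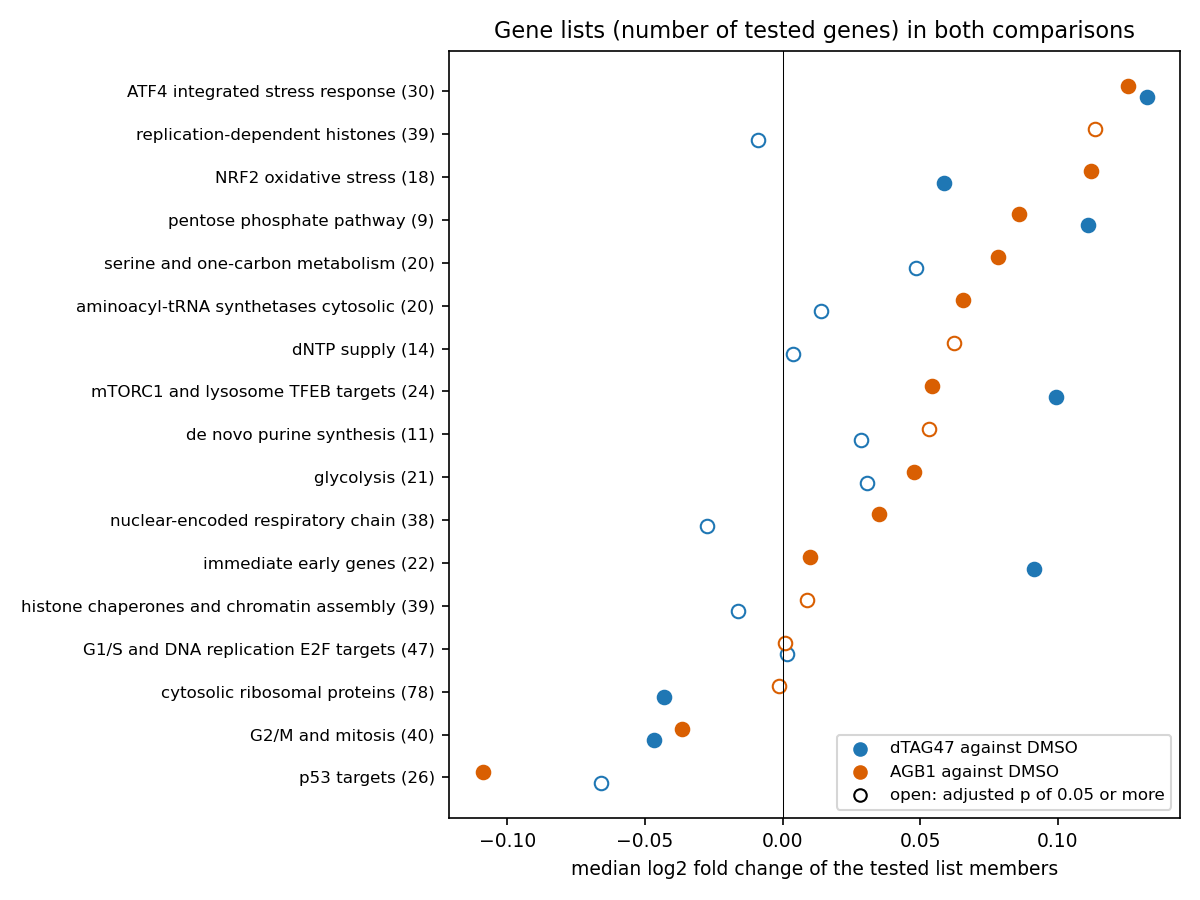
Median log2 fold change of the tested members of 17 gene lists with dTAG47 (blue) and AGB1 (orange) against DMSO; filled points have a camera adjusted p under 0.05 and open points do not, and the number of tested genes follows each name. ATF4 targets lie at 0.13 with both compounds, and p53 targets at −0.07 with dTAG47 and −0.11 with AGB1.

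dTAG47 and AGB1 were then compared directly, which asks whether the responses differ. No single gene passed: edgeR called 0 genes, with 736 at an unadjusted p under 0.05 where 916 would be given by chance, and DESeq2 and limma also called 0 (818 and 727 unadjusted). Of the genes above, HMOX1 was at −0.07 (SE 0.08), CHAC1 at −0.02 (SE 0.15), WNT5A at −0.04 (SE 0.09) and SEMA3C at 0.27 (SE 0.10), while MRPL23 was at 0.48 (SE 0.12), GPR89B at −0.35 (SE 0.19) and U2AF1 at −1.14 (SE 0.38). MYC was at −0.16 (SE 0.06, edgeR adjusted p = 0.999). Without a count filter edgeR called 13 genes, MRPL23, U2AF1, U2AF1L5 and the near-copies EIF3C and EIF3CL among them, and EIF3C and MAGED4B were called without AGB1 1 and AL591846.1 without dTAG47 1.

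Ribosomal protein genes were lower with dTAG47 than with AGB1 in 65 of 78 (median −0.05, camera adjusted p = 4.14e-06, and adjusted p = 0.681 with an estimated correlation), for instance RPS29 at −0.24 (SE 0.07) and RPLP0 at −0.10 (SE 0.04). NRF2 targets were lower in 16 of 18 (median −0.07, camera adjusted p = 0.00154, and adjusted p = 0.205 with an estimated correlation), with TXN at −0.12 (SE 0.05) and PRDX1 at −0.11 (SE 0.05). Respiratory chain genes were lower in 30 of 38 (median −0.05, camera adjusted p = 0.010, and adjusted p = 0.659 with an estimated correlation). Replication-dependent histone genes, whose mRNAs lack poly(A) tails and are poorly captured by this selection, were lower in 28 of 39 (median −0.13, camera adjusted p = 0.0442, and adjusted p = 0.326 with an estimated correlation), with HIST1H1C at −0.23 (SE 0.09). Against DMSO the same histone list had a median of 0.11 with AGB1 (camera adjusted p = 0.0523) and −0.01 with dTAG47 (0.970). p53 targets were higher with dTAG47 than with AGB1 in 20 of 26 (median 0.06, camera adjusted p = 0.0442, and adjusted p = 0.444 with an estimated correlation), with BAX at 0.21 (SE 0.08). In these 5 lists 0 genes passed over all genes and 0 adjusted over the list alone, and 0 of the lists held with an estimated correlation. The ribosomal protein and NRF2 lists held without each library; the respiratory chain ended without AGB1 2 (0.0798), the histones without dTAG47 2 (0.0504), dTAG47 3 (0.106), AGB1 2 (0.0525) or AGB1 3 (0.110), and p53 targets without DMSO 2 (0.0523), dTAG47 2 (0.124), dTAG47 3 (0.106) or AGB1 1 (0.371). The histones also ended in DESeq2 (0.0650) and with the gene length trend removed (0.145), and p53 targets among protein-coding genes alone (0.0596) and with the replicate number as a block (0.0518).

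Some genes were called with both dTAG47 and AGB1. HMOX1, CHAC1, SLC7A5 and RHOB rose in both comparisons and WNT5A fell in both, 5 genes in all. With unchanged groups and shared controls all drawn anew, the mean was 0.0800 genes and the highest 2 over 50 simulations. Independent lists of these lengths would share 0.00328 genes higher and 0.00246 lower. Across the tested genes, which are not independent replicates, the fold changes correlated with r = 0.554 against 0.502 ± 0.0124 (SD) in the simulations; the covariance was 0.0860 against 0.0626, a difference of 0.0234. Among genes at 5 CPM or more, r was 0.633 against 0.499 and the covariance 0.0107 against 0.00638, a difference of 0.00432. The simulations drew genes independently, so their spread lacks trends shared by many genes, such as the GC trend of these libraries. Leaving out single libraries, on fewer samples, moved r from 0.461 without AGB1 3 to 0.706 without DMSO 3. The simulations kept every library, so the simulated 0.502 is not a reference for these fits with unequal groups. This range therefore does not bear on the excess in r. Because genes were drawn independently, the simulations do not decide whether the excesses above lie beyond chance. With 3 DMSO libraries the controls could not be split into parts of at least 2, so part of the excess may come from the shared controls. The count of 5 became 1 without DMSO 2, dTAG47 1 or AGB1 3, 2 without AGB1 2, 3 without DMSO 1 or dTAG47 3 and 13 without DMSO 3, and it was 19 in DESeq2, 11 with the GC trend removed and 2 in fits of the 2 groups alone.

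**Figure D3:**
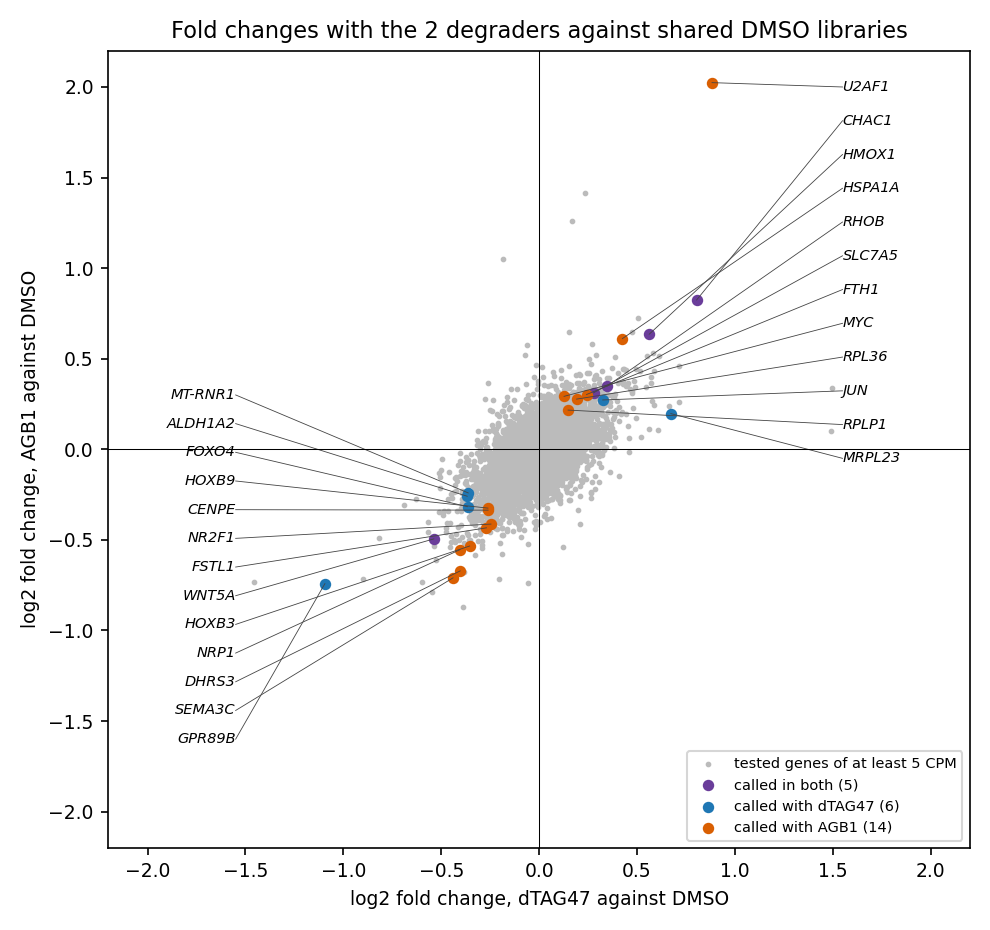
Log2 fold change with dTAG47 (horizontal) and with AGB1 (vertical) against the shared DMSO libraries for the genes at 5 CPM or more (grey, 11436 genes); genes past the threshold are coloured by the comparison that called them and joined by lines to their names. The 5 genes called in both comparisons are purple.

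Nucleotide synthesis genes showed no change past the threshold at the transcript level with either compound. De novo purine synthesis, the pathway that uses PRPP through PPAT, had 0 of 11 genes past the threshold over all genes and 0 adjusted over the list alone. Its median was 0.03 with dTAG47 (camera adjusted p = 0.853) and 0.05 with AGB1 (0.179); PPAT was at −0.10 (SE 0.06) and −0.09 (SE 0.06), and IMPDH2 at 0.03 (SE 0.05) and 0.06 (SE 0.05). De novo pyrimidine synthesis (6 genes) had camera adjusted p-values of 0.551 and 0.761, nucleotide salvage and breakdown (20 genes) 0.213 and 0.101, dNTP supply (14 genes) 0.695 and 0.0835, and the PRPP synthetase complex (4 genes) 0.853 and 0.470, each with 0 genes past the threshold in either adjustment. RRM2, the small subunit of ribonucleotide reductase, was at −0.04 (SE 0.06) and 0.06 (SE 0.06). G1/S and DNA replication genes (47 genes) gave 0.853 and 0.780, and DNA damage and replication stress genes (28 genes) 0.213 and 0.677, again with 0 genes in either adjustment.

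Chromatin genes likewise had 0 calls. Histone chaperones and chromatin assembly factors (39 genes) had medians of −0.02 with dTAG47 (camera adjusted p = 0.853) and 0.01 with AGB1 (0.652); ASF1B, which hands histones to the replication-coupled assembly machinery, was at −0.01 (SE 0.06) and 0.10 (SE 0.06). Replication-independent histone variants (12 genes) gave 0.583 and 0.179. Replication-dependent histones took 0.0320% ± 0.00284 of counts in DMSO, 0.0318% ± 0.00111 with dTAG47 and 0.0348% ± 0.000678 with AGB1 (SD, n = 3); the exact permutation p between dTAG47 and AGB1 was 0.1, the smallest that 3 against 3 libraries can give. In these 3 lists 0 genes passed over all genes and 0 adjusted over the list alone. Many histone genes are near-identical copies, so their separate counts are uncertain. Ribosome biogenesis genes (49 genes, 0 in either adjustment) gave 0.874 with dTAG47 and 0.0523 with AGB1, with medians of 0.01 and 0.04.

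Other fixed lists stayed short of the threshold in all 3 comparisons. The camera adjusted p-values with dTAG47 and with AGB1 were 0.387 and 0.626 for MYC and its partners, 0.105 and 0.0860 for hypoxia-inducible genes, 0.446 and 0.877 for cholesterol synthesis, 0.265 and 0.637 for fatty acid synthesis, 0.446 and 0.761 for the endoplasmic reticulum stress response, 0.792 and 0.481 for the heat shock response, 0.414 and 0.157 for interferon-induced genes, 0.853 and 0.416 for mitochondrially encoded mRNAs, and 0.478 and 0.943 for nuclear-retained or non-polyadenylated RNAs. Adjusted over the list alone, dTAG47 raised MNT (0.41), HSPA1A (0.43) and MT-ND3 (0.17), and AGB1 raised NDRG1 (0.30), STC2 (0.24), HSPA1A, HSPA1B (0.19), HSP90AB1 (0.12) and MYC and lowered STARD4 (−0.35). Over all genes, HSPA1A and MYC with AGB1 were the 2 calls in these lists. Markers of other cell types gave 0.853 and 0.629 for haematopoietic cells, 0.853 and 0.780 for fibroblasts and endothelium, 0.853 and 0.216 for neurons, 0.792 and 0.261 for differentiated kidney tubule, and 0.387 and 0.430 for keratin-rich carcinoma lines, with 0 calls over all genes. For the tubule list with dTAG47 the median (0.11) was positive and the test downward, and for MYC and its partners with AGB1 the median was −0.02 and the test upward. Adjusted over the list alone, the tubule gene LRP2 was lower with dTAG47 (−0.35) and AGB1 (−0.36), and with AGB1 the neurofilament gene NEFM was higher (0.21) and KRT8 lower (−0.28). In the direct comparison, KRT8 was higher (0.28) and the lysosomal galactosidase GLA lower (−0.17) with dTAG47 than with AGB1 when adjusted over the list alone.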

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

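The tests with the GC trend removed, with both compounds pooled against DMSO, and with copies summed were chosen after the data were seen. Of the values under other settings, 1431 kept their direction and side of the threshold (for counts, stayed within 1.5 times), 186 kept the direction but missed the threshold, 72 moved and 15 changed sign. For lists this direction is that of the test: the immediate early gene median with AGB1 (0.01) turned to −0.000653 on library sizes alone and −0.00478 with the GC trend removed while the test stayed upward. DESeq2 gave 23 genes higher and 24 lower with dTAG47, 32 and 49 with AGB1, and 19 in both; the cause was not tested. No count filter gave 21 and 22, 23 and 44, and 21 in both, with 4 higher and 9 lower between dTAG47 and AGB1, among 33037 tested genes; the cause was not tested. Fits of the 2 groups alone gave 1 higher and 3 lower with dTAG47 and 2 in both, on fewer samples. With AGB1 they called 22 and kept all 19, so fewer samples alone do not account for the loss with dTAG47. Chi-square per degree of freedom was 6.05 to 6.39 within AGB1, 7.97 to 14.8 within dTAG47 and 9.44 to 16.3 within DMSO. The fit of all 9 libraries shares one spread, so its p-values for dTAG47 against DMSO may be too small, which was not tested. GC trend removal gave 14 lower with dTAG47, 23 higher and 24 lower with AGB1 and 11 in both; the cause was not tested. An adjusted p under 0.01 in both left 1 gene, by the stricter threshold. The correlation estimated per list left 0 lists with dTAG47, 1 with AGB1 and 0 between them. With dTAG47 the estimate was −0.0159 for NRF2 and −0.0424 for mTORC1 and TFEB targets, under the preset 0.01. Their camera adjusted p still rose to 0.108, so a higher correlation did not end these lists. Under that setting camera also refers its statistic to the residual degrees of freedom of the 9 libraries, rather than to those of the tested genes. A list that ended there therefore need not have ended through correlation between its genes, and the 2 parts were not separated. Values near 0 changed sign: PRPS2 between dTAG47 and AGB1 was 0.00493 on library sizes alone, 0.000759 with no count filter and 0.0141 with the GC trend removed; PRPSAP1 was 0.00872 with AGB1 with the length trend removed and a replicate block, and −0.00386 with dTAG47 with upper-quartile factors; the cause was not tested. Leaving out each library, on fewer samples, gave 1 to 15 genes higher and 0 to 5 lower with dTAG47, 2 to 24 and 4 to 31 with AGB1, 0 to 1 and 0 to 2 between them, and 1 to 13 in both (totals by library are in the report). It gave r from 0.461 without AGB1 3 to 0.706 without DMSO 3, 3 to 13 lists with AGB1, 3 to 6 between the compounds, PRPS1 between them from −0.00962 to 0.0320, PRPSAP1 from −0.159 to 0.168 with AGB1, −0.133 to 0.193 with dTAG47 and −0.0350 to 0.0890 between them, and PRPSAP2 with dTAG47 from −0.0511 to 0.00694. The highest gene totals came without DMSO 3 (20 with dTAG47 and 55 with AGB1), a rise that fewer samples alone do not account for. DMSO 3 had a GC rho of 0.271, against −0.378 in DMSO 1 and −0.280 in DMSO 2, and the cause of the rise was not tested. A replicate number as a block gave 10 and 17 genes, losing ALDH1A2, MYC and HOXB3. For 0 libraries did deviations correlate better with both libraries of their own number than with every other library of the other groups. DMSO 2 did correlate best with dTAG47 2 (0.0175) and AGB1 1 with dTAG47 1 (0.0110), but both values were small. The numbers were not treated as pairs. At the lowest depth a count of 3 is 0.107 CPM. Of the genes given the smallest simulated change, all with a mean of at least 1 CPM, 38.8% were recovered. That fit called 137 genes, so recovery in the real comparisons, with fewer calls, may be lower.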

Other observations

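The chance tests on ATF4 and HOX genes, the sums of GPR89B and U2AF1 with their copies, the 3 developmental lists, the GC trend removals, the GC refit of 1 split and the pooled comparison of both compounds with DMSO were tests chosen after the results were seen.

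With the 6 compound-treated libraries pooled, 11 genes were higher and 25 lower than in DMSO (edgeR, 1618 genes at an unadjusted p under 0.05), and 14 of the 36 had been called in neither single comparison. SESN2, a stress-induced regulator of mTORC1, was higher (0.26, SE 0.05). The homeobox genes HOXC4 (−0.57, SE 0.12) and HOXC9 (−0.51, SE 0.11), their cofactor PBX3 (−0.41, SE 0.09), the antisense transcript HOXB-AS3 (−0.66, SE 0.14), the corepressor TLE4 (−0.29, SE 0.06) and the chromatin protein gene HMGA2 (−0.28, SE 0.06) were lower, as were ZNF608 (−0.47), ARGLU1 (−0.29), ADD3 (−0.27) and the transcript AC091182.1 (−0.66). PKD1P1 and FP236383.2, also lower, share 97.6% and 100% of their words with copies. HOXC4, HOXC9 and HOXB-AS3 overlap neighbours, so their counts are uncertain. The counts were 4 and 15 without DMSO 1, 6 and 10 without DMSO 2, 40 and 44 without DMSO 3, 10 and 15 without AGB1 1, 7 and 14 without AGB1 2, and 6 and 11 without AGB1 3. In 1 of the 84 splits of the 9 libraries into 3 and 6, the real one, as many genes were called (36, against 23 in the highest other). The pooled comparison was chosen after results on these same libraries were seen, so this rank does not exclude chance for the gene count. As many lists were called in 7 of the 84 splits (8, against 10 in the highest other), so chance cannot be excluded for them either. With an estimated correlation the smallest camera adjusted p of any list in the pooled fit was 0.0634, for ATF4 targets.

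For single comparisons the 10 splits of 6 libraries are too few for a share under 0.05. The real values and the highest others were 11 and 27 genes with dTAG47 (2 splits as large), 7 and 4 lists (1), 19 and 3 genes with AGB1 (1), 12 and 8 lists (1), and between dTAG47 and AGB1 0 and 4 genes (10) and 5 and 2 lists (1). The split with 27 genes sets DMSO 1, DMSO 2 and dTAG47 2 against DMSO 3, dTAG47 1 and dTAG47 3, which parts the libraries with a negative GC trend (rho −0.378, −0.280 and −0.329) from those with a positive one (0.271, 0.623 and 0.0289). With the GC trend removed this split called 0 genes (edgeR, 1227 at an unadjusted p under 0.05, against 2399 before; no other tool was run on it), so the trend may account for its calls, while the 11 real calls were kept among 22. For 100 splits into 3 groups, the real one among them, 2 gave as many genes called in both comparisons (5, highest other 5). As large a correlation came from 4 of them (0.554, highest other 0.566). The 100 are a random sample of the possible splits, so shares this close to 0.05 do not exclude chance regrouping for either.

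ATF4 and NRF2 targets were higher with both compounds at the preset correlation, but with an estimated correlation only NRF2 with AGB1 passed (adjusted p = 0.0124; ATF4 with AGB1 0.0501, both with dTAG47 0.108, pooled 0.0634 and 0.166). The mean log2 CPM of the 30 ATF4 genes was 5.56 ± 0.0514 in DMSO, 5.68 ± 0.0472 with dTAG47 and 5.70 ± 0.0235 with AGB1 (SD, n = 3), with the DMSO libraries the lowest 3 of 9 (exact permutation p = 0.0119, the smallest that 84 choices can give). For NRF2 genes it was 6.03 ± 0.0128, 6.13 ± 0.00508 and 6.23 ± 0.0106, with the DMSO libraries again the lowest 3. Both lists were picked out on these same libraries, so this leaves chance values of the shared DMSO libraries open. With AGB1 the ATF4 list median was 0.110 after GC trend removal and 0.117 after gene length trend removal, against 0.126 before, which argues against either trend as the whole cause. A response to loss of either protein, to the compounds or to ligase recruitment, and differences in culture or handling, also stay open; no untagged cells were treated, and the design does not separate these.

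Reads shared with copies may account for the GPR89B call. Summed with GPR89A, GPR89B with dTAG47 went from −1.09 (SE 0.18) to −0.27 (SE 0.15, edgeR adjusted p = 0.738), so the call ended because the fold shrank. For HSPA1A with AGB1 the sum with HSPA1B (0.22, SE 0.06, edgeR adjusted p = 0.269) decides nothing, since a change in HSPA1A alone would move it by only 0.04. U2AF1 summed with U2AF1L5 stayed past the threshold with AGB1 (1.69, SE 0.21, edgeR adjusted p = 6.33e-05), so a shift of reads between these genes does not account for the call. U2AF1L5 itself varied widely between the AGB1 libraries (26.2 ± 32.7 CPM without TMM scaling), which the sum carries over. Of the 2 genes sharing words with U2AF1, only U2AF1L5 was summed with it. The counting tool is not given, so reads matching both genes may be missing from the sum, which cannot show their effect. The longest transcript of MRPL23 shares 0% of its words with other genes, and its exonic bases outside that transcript were not searched for shared words. Of all its exonic bases, 2.86% lie in exons of the opposite-strand gene MRPL23-AS1. U2AF1 in AGB1 3 lay within the DMSO range and the call ended without DMSO 1, DMSO 2 or AGB1 2, and MRPL23 ended without DMSO 2 or dTAG47 1, so both rest on few libraries. No biological explanation was tested.

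Pooled, 4 of 37 HOX and 4 of 26 retinoic acid genes were called, all lower (edgeR), a pattern noticed in these calls and then tested on the same libraries with the list members that had not been seen, of which 0 passed. Of the 33 unseen HOX genes 31 were negative pooled (camera p = 2.69e-14, with an estimated correlation 0.00144), as were 17 of 21 retinoic acid genes (5.76e-06, 0.00284) and 24 of 34 developmental signalling genes (0.0186, 0.0517); unseen members co-vary with those seen, so these are not independent tests. The median of all 37 HOX genes was −0.31 with the GC trend removed against −0.29 before, and the unseen genes' mean log2 CPM was higher in the 3 DMSO libraries (3.23 ± 0.121, lowest 3.09) than in the treated ones (2.93 ± 0.0801 and 2.94 ± 0.0772, highest 3.02; exact permutation p = 0.0119, the smallest possible), whereas for retinoic acid genes DMSO 2 (3.58) lay below dTAG47 2 (3.60). The first argues against that trend, while chance values of the DMSO libraries stay open, since the pattern was noticed against the same libraries. Between dTAG47 and AGB1 the HOX list had a camera p of 0.904. The compounds, the depletions and differences between cultures stay open.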
